A study of Homo sapiens with 9 samples.

How the data were processed

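RNA was sequenced from HaCaT cells, an immortalised human keratinocyte line, in 9 libraries. The groups were 1% DMSO (the vehicle control), 250 nM CDDO-Me and 10 µM PRL-295, each for 14 h with 3 libraries. CDDO-Me (bardoxolone methyl) is an electrophilic triterpenoid that activates NRF2, the transcription factor of the cell's antioxidant response. PRL-295 is known here by its code name only, and the study's title calls the activators of its interest non-electrophilic. The labels list DMSO for the control group only, and whether the compound cultures held it is not given. Whether the libraries of a group came from separate cultures is not given either, so every p-value measures the spread between samples only.

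Per the labels, RNA was taken with a Qiagen RNeasy Plus kit, and paired-end reads were aligned to hg38 with STAR 2.5 and counted per gene with HTSeq 0.6.1. The same text names TopHat, Cufflinks, DESeq2, edgeR, STAR-Fusion 0.8.0, Picard 1.111, SAMtools 0.1.18 and GATK without their role in these tables. The labels state neither the annotation release nor the strand setting. The deposited counts are raw reads per gene, and all of them were whole numbers. The deposited FPKM equalled the count divided by gene length in kilobases and by the library total of counts, scaled as the unit's name says, for 100% of values within 0.1%. The authors' group FPKM equalled the mean of the group's 3 samples, with a largest deviation of 5e-10%. The gene length in bases came from the deposited tables. Tables with and without gene names held the same values, with 0 differences. All 58676 genes had an identifier in GENCODE release 29; 55921 had the same start and end there, and 36760 the same name, so the deposited names were used.

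Library totals ran from 23383800 to 32942156 counted reads. A floor of 3 counts corresponds to 0.0911 to 0.128 CPM (counts-per-million), depending on the library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

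Counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with filterByExpr by group and TMM scaling, in a single fit of all 9 libraries. Benjamini-Hochberg adjustment was applied over 16239 tested genes in each of 3 comparisons, with a threshold of 0.05. The third comparison set PRL-295 directly against CDDO-Me. An F test asked whether a gene differed among the 3 groups. Intervals beside fold changes are 95% intervals of the log2 fold change from the same fit. CPM are given as mean ± SD, n = 3.

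The 31 gene lists (416 symbols, all matched) and the rule for named genes were set before the data were examined. Among them are 4 lists of markers of other cell types, for fibroblasts, melanocytes, immune cells and endothelial cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over 93 tests. Camera compares a list with the other tested genes. It was also run with the correlation estimated from the data, and fry was run beside it. Fry's directional p tests whether a list's genes move on balance 1 way, and its mixed p tests change in either direction, and neither compares a list with other genes. With an estimated correlation, 9 of 13 list calls held for CDDO-Me against DMSO, 9 of 13 for PRL-295 against DMSO and 3 of 13 for the direct comparison. For each comparison, the named genes were the 10 largest rises and the 10 largest falls past the threshold, with a mean of at least 1 CPM and no overlap between groups. Up to 4 called members of each list with the largest change were added, or, where none was called, the 2 with the highest CPM. A panel of 13 NRF2 pathway genes, 1 of which is not reported here, was named whatever its values, as were, among genes called for either compound and past the direct test, the 10 with the largest difference in each direction. A further retinoid list is described with its test under the other observations.

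The pipeline was tested on simulated data at the depth of these libraries, with 50 genes changed per fold size, all with a mean of at least 1 CPM. Genes were drawn independently, with each gene's spread equal in all groups and no GC trend. The real groups differed in spread (median SD of log2 CPM 0.146 in DMSO, 0.244 in CDDO-Me and 0.146 in PRL-295) and libraries in GC trend. The simulated shares and false calls do not cover that. For CDDO-Me against DMSO it recovered 4% of genes changed 1.5-fold, 56% at 2-fold, 84% at 4-fold and 92% at 8-fold, with 2 false calls. For PRL-295 against DMSO the shares were 10%, 56%, 78% and 90%, with 7 false calls.

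Alternatives were DESeq2 1.42.0, RLE and library-size scaling, no filter or a minimum of 1 CPM, a fold threshold of 2, limma on log2 FPKM with a pseudocount of 1 or 0.1, a replicate block, fits of 6 libraries only and leaving out each library. A correction of each library for GC content and gene length was added after the libraries were seen to differ in both. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The group FPKM tables were used for the check only.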

Results

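Gene expression was measured by RNA sequencing in HaCaT keratinocytes after 14 h with 1% DMSO, 250 nM CDDO-Me or 10 µM PRL-295, with 3 libraries per group. Counted reads were 24239976, 32942156 and 31739895 in DMSO libraries 1 to 3, 31897090, 29123052 and 23383800 in CDDO-Me libraries 1 to 3, and 24338972, 27084070 and 27375327 in PRL-295 libraries 1 to 3. The number of genes with at least 1 count ran from 14543 in CDDO-Me 1 to 23271 in CDDO-Me 2. Mitochondrially encoded genes took 3.71% to 5.23% of the counts. Across genes, each library's deviation from the mean of all 9 followed GC content to a different degree. The correlations were 0.532, 0.494 and 0.431 in DMSO libraries 1 to 3 and 0.0615, -0.728 and -0.346 in CDDO-Me libraries 1 to 3. In PRL-295 libraries 1 to 3 they were -0.632, 0.339 and -0.266. The GC trend thus differed between DMSO and the compounds, so it is partly confounded with both comparisons against DMSO. Within their groups, CDDO-Me 2 (-0.684) and PRL-295 1 (-0.582) stood at one end and PRL-295 2 (0.515) and CDDO-Me 1 (0.456) at the other.

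CDDO-Me against DMSO asked which genes the electrophilic NRF2 activator changes in keratinocytes. The antioxidant and detoxification genes that NRF2 is known to control rose together. HMOX1, the heme-degrading enzyme heme oxygenase 1 (ENSG00000100292; hg38 chromosome 22, 35380361 to 35394214), rose from 11.1 ± 2.47 CPM with DMSO to 362 ± 9.49 CPM with CDDO-Me, which is 32.5-fold. Interferon-stimulated genes, a set of antiviral genes, fell. Genes of basal keratinocytes and of the wound edge rose, while the stem-cell associated keratin KRT15 fell by 2.97 on the log2 scale.

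Of 41 tested NRF2 targets, 27 rose with CDDO-Me and none fell (30 rose adjusted over the list alone), with a median log2 fold change of 0.995. The camera adjusted p was 8.12e-70 at the preset correlation and 0.00758 with an estimated correlation. Among the genes of quinone and carbonyl detoxification, 10 of 18 rose (14 adjusted over the list alone), including the aldo-keto reductases AKR1C1 (log2 fold change 4.38, adjusted p = 1.81e-07) and AKR1B10 (2.63, adjusted p = 6.93e-06). AKR1C1, AKR1C2 and AKR1C3 are close paralogs with overlapping annotation, so the share of each is uncertain. NQO1, the quinone reductase often used as a readout of NRF2 (ENSG00000181019; chromosome 16, 69706996 to 69726951), rose from 371 ± 41.8 to 739 ± 176 CPM (adjusted p = 0.00771, and 0.0503 without DMSO 2). In the glutathione list, 5 of 10 rose (5 up and 2 down adjusted over the list alone), among them the cystine transporter SLC7A11 (log2 fold change 3.30) and the subunits of the enzyme that starts glutathione synthesis, GCLC (1.89) and GCLM (1.49). SLC7A11 overlaps an antisense gene that was also tested, and the strand setting of the counts is not stated. In the thioredoxin and peroxide list, 3 of 8 rose (4 adjusted over the list alone), with thioredoxin reductase TXNRD1 at 2.11 and the oxidative stress inhibitor of growth OSGIN1 at 2.67 on the log2 scale. In the heme and iron list, 4 of 8 rose, HMOX1 and the ferritin light chain gene FTL (0.94, uncertain because of its pseudogenes) among them, and 4 did so adjusted over the list alone. In the NADPH and pentose phosphate list, 4 of 6 rose over all genes and adjusted over the list alone, including PGD (1.28) and ME1 (1.32), which make NADPH (adjusted p of the list 1.02e-07; adjusted p = 0.054 with an estimated correlation). Of 6 drug efflux transporters, 2 rose (3 adjusted over the list alone), namely ABCC2 (1.36) and ABCC3 (1.16). Of 10 regulators of the pathway, 2 rose (3 adjusted over the list alone), the NRF2 antagonist BACH1 (1.82) and its partner MAFG (0.83), with a list adjusted p of 0.00322 and an adjusted p = 0.054 with an estimated correlation. The camera adjusted p was 3.43e-33 for the quinone and carbonyl list, 6.52e-09 for glutathione, 1.68e-12 for thioredoxin and peroxide, 1.22e-11 for heme and iron and 0.00031 for efflux. With an estimated correlation these were 0.0131, 0.0342, 0.0131, 0.0131 and 0.0342. NFE2L2, which encodes NRF2, had a log2 fold change of 0.68 (adjusted p = 0.192), and its inhibitor KEAP1 0.18 (adjusted p = 0.398).

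**Figure D1:**
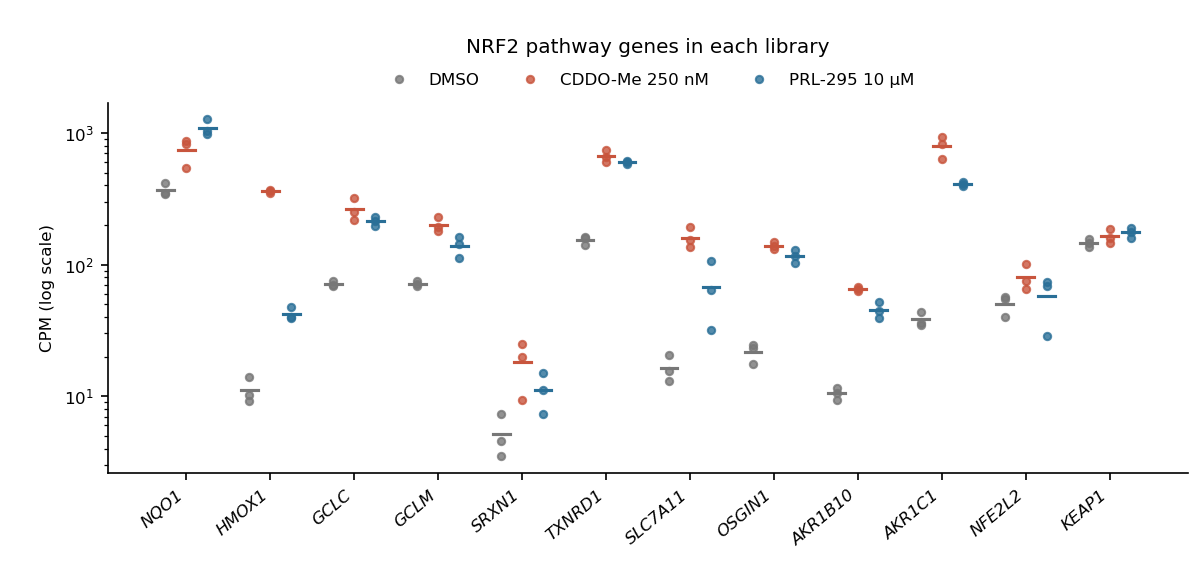
CPM (log scale) of panel genes of the NRF2 pathway in each of the 9 libraries, by group. HMOX1 lies at 362 ± 9.49 CPM with CDDO-Me and 42.1 ± 4.82 CPM with PRL-295, against 11.1 ± 2.47 CPM with DMSO.

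Of 22 interferon-stimulated genes, 14 fell with CDDO-Me and none rose (18 fell adjusted over the list alone), with a median of -1.001 on the log2 scale (camera adjusted p = 2.99e-20, and 0.0342 with an estimated correlation). Examples were IFIT3, an inhibitor of viral replication (log2 fold change -1.47, adjusted p = 0.000262), the antiviral GTPase MX2 (-1.58, adjusted p = 0.00215) and BST2, which tethers viruses to the cell (-2.48, adjusted p = 0.00158). Of 13 genes of basal keratinocytes and hemidesmosomes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 2.1e-05, and 0.0342 with an estimated correlation). The integrin subunit ITGA6 rose by 1.76 on the log2 scale (adjusted p = 5.61e-05), and KRT15 (ENSG00000171346) was the gene that fell (adjusted p = 4.08e-06). Of 27 wound edge and migration genes, 10 rose and none fell (16 and 1 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 2.12e-08, and 0.0171 with an estimated correlation). They included the collagenase gene MMP1 (1.77), the growth factor AREG (1.72) and KRT16, a keratin of activated keratinocytes (1.61, adjusted p = 0.0108). Of 14 growth and angiogenic factors, 5 rose and 1 fell (6 and 2 adjusted over the list alone), with BMP4 at 1.68 and VEGFC at 1.01 (list adjusted p = 0.00472; adjusted p = 0.0758 with an estimated correlation). Of 18 genes of DNA replication, 4 fell (5 adjusted over the list alone), among them MCM2 (-0.67) and MCM3 (-0.53), subunits of the replicative helicase (list adjusted p = 0.0394; adjusted p = 0.399 with an estimated correlation). The replication call ended without DMSO 2 (0.0817) or CDDO-Me 3 (0.0902), the MCM2 call without DMSO 1 (0.0585) or DMSO 2 (0.0621), and the MCM3 call without DMSO 2 (0.0699), DMSO 3 (0.0579) or CDDO-Me 2 (0.0544).

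Among lists that camera did not call for CDDO-Me, 5 of 26 proteasome subunits rose over all genes and over the list alone (list adjusted p = 0.0936), and 3 of 14 p53 targets rose (4 up and 1 down adjusted over the list alone; list adjusted p = 0.0818). Both lists were called upward with a GC and length correction (adjusted p = 0.033 and 0.00817) and without a filter, the proteasome list also without DMSO 3 or without CDDO-Me 1, and the p53 list with fry (0.000101). With an estimated correlation neither was (0.604 and 0.187), so whether they rose stays open. Camera with the GC and length correction also called the heat shock (adjusted p = 0.000418) and glycolysis and hypoxia (0.0297) lists upward. It called the fatty acid synthesis list downward (0.0162). Without the correction these 3 lists had 0.149, 0.314 and 0.0722, and with an estimated correlation 0.41, 0.533 and 0.187. Of 18 cholesterol genes 4 rose and 2 fell (5 and 3 adjusted over the list alone; list adjusted p = 0.564), and of 19 inflammatory genes 1 rose and 4 fell (3 and 5; list adjusted p = 0.132).

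Among called genes with a mean of at least 1 CPM, the largest fall with CDDO-Me was in STRA6, a receptor for retinol uptake (ENSG00000137868; chromosome 15, 74179466 to 74212267), at 11.5 ± 3.39 CPM with DMSO and 0.082 ± 0.108 CPM with CDDO-Me (adjusted p = 0.000157). The epithelial transcription factor gene ELF3 (-5.14), the chemokine gene CCL2 (-4.08) and the retinal reductase gene DHRS3 (-3.66) also fell. CYP1A1, a target of the aryl hydrocarbon receptor (ENSG00000140465; chromosome 15, 74719542 to 74725610), fell from 14.0 ± 1.44 to 4.66 ± 0.92 CPM (adjusted p = 0.00145). TIPARP, another of the 4 targets listed for that receptor, rose (log2 fold change 1.11, adjusted p = 0.000904), and the list was not called (1 up and 1 down, also adjusted over the list alone; median 0.42, mean 0.09, camera adjusted p = 0.631). SREBF1, a transcription factor of lipid synthesis, fell by 1.29 on the log2 scale (adjusted p = 0.000641).

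The edgeR quasi-likelihood test called 1497 of 16239 genes for CDDO-Me against DMSO, 755 higher and 742 lower (Benjamini-Hochberg adjusted), of which 352 and 166 changed at least 2-fold. The genes called higher had a median GC content of 42.4% and those called lower 57.2%, against 49.2% of all tested genes, and after a GC and length correction 838 of the 1497 calls remained among 1392. The count was 477 without DMSO 1, 400 without DMSO 2, 628 without DMSO 3, 2803 without CDDO-Me 1, 629 without CDDO-Me 2, 946 without CDDO-Me 3 and 779 without PRL-295 3.

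PRL-295 against DMSO asked which genes the other compound changes in the same cells. The antioxidant and detoxification genes of NRF2 rose here as well. NQO1 rose from 371 ± 41.8 to 1090 ± 155 CPM (2.94-fold), and HMOX1 from 11.1 ± 2.47 to 42.1 ± 4.82 CPM (3.78-fold). Interferon-stimulated genes fell as a list. CYP1A1 rose from 14.0 ± 1.44 to 50.2 ± 9.76 CPM.

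Of the 41 NRF2 targets, 24 rose with PRL-295 and none fell (33 rose adjusted over the list alone), with a median of 0.98 on the log2 scale. The camera adjusted p was 1.97e-116 at the preset correlation and 0.00341 with an estimated correlation. Of 18 quinone and carbonyl detoxification genes, 10 rose (16 adjusted over the list alone), with AKR1C1 at 3.41 (adjusted p = 3.41e-06), AKR1B10 at 2.10 (adjusted p = 8.66e-05) and NQO1 at 1.55 (adjusted p = 0.00219). In the glutathione list 5 of 10 rose (5 up and 1 down adjusted over the list alone), including GCLC (1.58), glutathione reductase GSR (1.11) and the glutathione peroxidase GPX2 (1.00). In the thioredoxin list 2 of 8 rose (5 adjusted over the list alone), TXNRD1 (1.97) and OSGIN1 (2.41). In the heme and iron list 3 of 8 rose over all genes and adjusted over the list alone, HMOX1 (1.92), FTL (0.98) and the heme synthesis enzyme FECH (1.06). In the NADPH and pentose phosphate list 4 of 6 rose (5 adjusted over the list alone), PGD (1.31) among them. Of 6 drug efflux transporters 1 rose (2 adjusted over the list alone), ABCC3 at 0.65 (list adjusted p = 0.00419; adjusted p = 0.064 with an estimated correlation). Leaving out any of DMSO 1 (0.16), DMSO 2 (0.193), DMSO 3 (0.124), CDDO-Me 3 (0.0683), PRL-295 1 (0.148), PRL-295 2 (0.0645) or PRL-295 3 (0.157) ended the ABCC3 call. Of 10 regulators 1 rose (2 adjusted over the list alone), MAFG at 0.80 (list adjusted p = 0.00145, and 0.0455 with an estimated correlation), and that gene's call ended without DMSO 2 (0.119), DMSO 3 (0.0706), PRL-295 2 (0.0508) or PRL-295 3 (0.0985). The camera adjusted p was 1.8e-63 for the quinone and carbonyl list, 2.12e-13 for glutathione, 1.85e-20 for thioredoxin and peroxide, 8.48e-13 for heme and iron and 1.3e-19 for NADPH and pentose phosphate. With an estimated correlation these were 0.00932, 0.0131, 0.00945, 0.0131 and 0.0131. NFE2L2 (0.18, adjusted p = 0.888) and KEAP1 (0.28, adjusted p = 0.379) did not pass. Of 4 aryl hydrocarbon receptor targets 2 rose (3 adjusted over the list alone), CYP1A1 (1.85, adjusted p = 0.00188) and the receptor's repressor TIPARP (1.05), with a camera adjusted p of 3.69e-07 (0.0131 with an estimated correlation). None of the 26 proteasome subunits passed over all genes, and 7 were higher adjusted over the list alone, with a median of 0.31 (list adjusted p = 2.65e-06; adjusted p = 0.201 with an estimated correlation).

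Of the 22 interferon-stimulated genes, 5 fell with PRL-295 and none rose (16 fell adjusted over the list alone), with a median of -0.71 (camera adjusted p = 4.9e-22, and 0.0342 with an estimated correlation). Outside the list, OASL, a relative of the antiviral OAS enzymes, fell by 1.32 on the log2 scale (adjusted p = 0.00483). MX2 fell by 1.46 on the log2 scale (adjusted p = 0.0158), a call that ended without DMSO 1 (0.069), DMSO 2 (0.0758), DMSO 3 (0.0657), PRL-295 2 (0.052) or PRL-295 3 (0.0815). Of 21 differentiation genes, 2 fell and none rose (3 fell adjusted over the list alone), with a median of -0.67 (list adjusted p = 7.81e-05; adjusted p = 0.0845 with an estimated correlation). The median was -0.34 without DMSO 1 and -0.44 without PRL-295 2. They were KRT1, a keratin of suprabasal cells (ENSG00000167768; chromosome 12, 52674736 to 52680407; log2 fold change -4.50, adjusted p = 0.0352), and IVL, a precursor of the cornified envelope (-1.42, adjusted p = 0.0312). KRT1 stood at 101, 7.65 and 49.2 CPM in DMSO libraries 1 to 3, and its call ended without DMSO 1 (0.146), DMSO 3 (0.084), CDDO-Me 3 (0.0593), PRL-295 1 (0.12), PRL-295 2 (0.127) or PRL-295 3 (0.147). The IVL call ended without DMSO 1 (0.126), DMSO 3 (0.0706), CDDO-Me 3 (0.0638), PRL-295 1 (0.145), PRL-295 2 (0.105) or PRL-295 3 (0.1). Of 27 wound edge genes, 2 rose and 1 fell (6 and 2 adjusted over the list alone; list adjusted p = 0.317), and of 13 basal genes none rose and KRT15 fell (3 up and 3 down adjusted over the list alone; list adjusted p = 0.406). KRT15 fell by 1.09 on the log2 scale (adjusted p = 0.00702), with 0.0503 without DMSO 1 and 0.0709 without PRL-295 3. None of the 12 mitochondrially encoded genes passed over all genes or adjusted over the list alone, and the list's median was 0.25 (list adjusted p = 0.00609; adjusted p = 0.484 with an estimated correlation). That list call ended without DMSO 1 (median 0.13, adjusted p = 0.0801), and with a GC and length correction the median was -0.15 (adjusted p = 0.251).

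**Figure D2:**
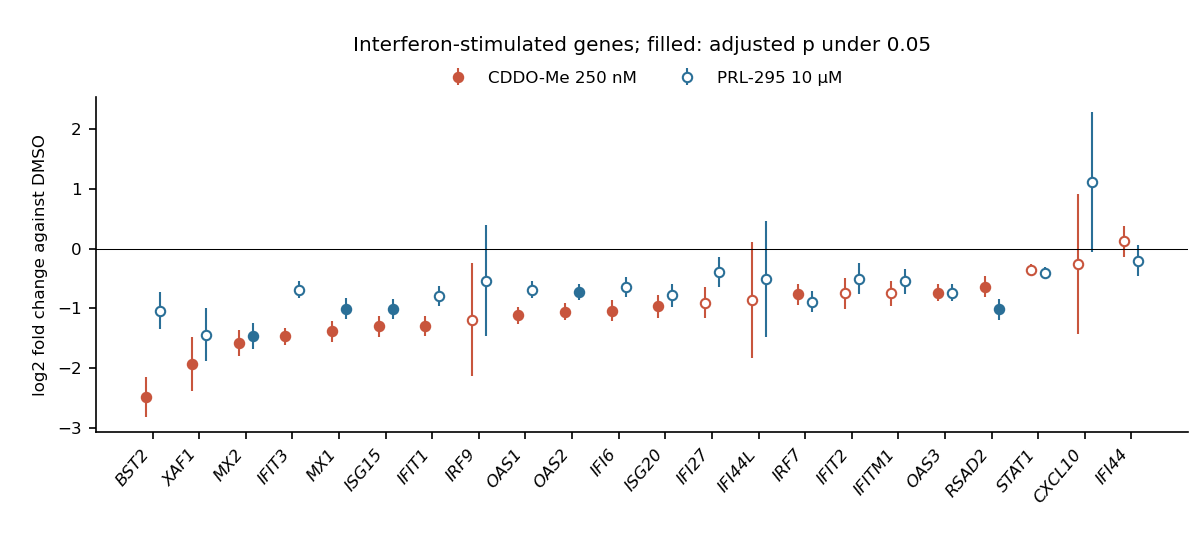
Log2 fold change against DMSO of each of the 22 interferon-stimulated genes with CDDO-Me and PRL-295; filled points passed the edgeR threshold. With CDDO-Me 14 genes fell and with PRL-295 5 did.

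For PRL-295 against DMSO, edgeR called 111 genes, 75 higher and 36 lower, of which 42 and 20 changed at least 2-fold; 2093 genes had an unadjusted p under 0.05. The genes called higher had a median GC content of 45.7% and those called lower 53.3%, and after a GC and length correction 104 of the 111 calls remained among 266. The count was 36, 40 and 50 without DMSO 1, 2 and 3, 589, 272 and 62 without CDDO-Me 1, 2 and 3, and 42, 59 and 33 without PRL-295 1, 2 and 3. Few lower calls remained in some fits. There were 31 higher and 2 lower without PRL-295 3, 32 and 4 without DMSO 1, 37 and 5 without PRL-295 1, and 50 and 10 with a replicate block. Without CDDO-Me 1 there were 430 and 159, and in a fit of only the 6 libraries compared 494 and 156.

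PRL-295 against CDDO-Me asked directly where the compounds differ, at doses that differ (10 µM and 250 nM). HMOX1 was 8.59-fold lower with PRL-295 than with CDDO-Me. Genes of the basal layer and of the wound edge were lower with PRL-295, KRT16, ITGA6 and KRT14 among them. CYP1A1 was 10.8-fold higher with PRL-295, and STRA6, DHRS3, ELF3 and CCL2 were higher too.

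Most NRF2 targets did not pass the direct test. Of 41, none was higher with PRL-295 and 2 were lower (3 and 9 adjusted over the list alone), with a median of -0.03 and a mean of -0.17 (list adjusted p = 0.00977; adjusted p = 0.418 with an estimated correlation). This list call also ended without CDDO-Me 2 (0.0552), PRL-295 1 (0.127) or PRL-295 3 (0.0771), where the median was 0.09, 0.05 and 0.08, and the median was 0.04 without CDDO-Me 3. With a GC and length correction the list had a median of -0.13 (adjusted p = 1.49e-06), with 8 genes lower and 1 higher. The 2 lower genes were HMOX1 (log2 fold change -3.10, adjusted p = 1.16e-05) and AKR1C1 (-0.97, adjusted p = 0.00777, and 0.0761 without PRL-295 3). NQO1 differed by 0.56 (95% interval 0.18 to 0.94, adjusted p = 0.137), TXNRD1 by -0.14 (-0.37 to 0.09) and OSGIN1 by -0.26 (-0.58 to 0.05), each short of the threshold. In the heme and iron list HMOX1 alone was lower (2 adjusted over the list alone), and the list's test was downward with a mean of -0.29, although its median was 0.14 (list adjusted p = 0.00582; adjusted p = 0.114 with an estimated correlation; 0.0754 without PRL-295 1). Its median was 0.06 without CDDO-Me 1, 0.08 without PRL-295 2 and 0.22 without PRL-295 3. The aryl hydrocarbon receptor list was higher with PRL-295 (camera adjusted p = 0.0011, and 0.0455 with an estimated correlation), with 1 of 4 genes past the threshold over all genes and over the list alone, CYP1A1 (log2 fold change 3.43, adjusted p = 6.12e-05). Of its 4 genes 2 lay above 0, with a mean of 0.74 and a median of 0.10, which was 0.25, 0.26 and 0.01 without CDDO-Me 1, 2 and 3, -0.05 without PRL-295 1 and 0.27 without PRL-295 2.

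Of 13 basal keratinocyte genes, 6 were lower with PRL-295 than with CDDO-Me and 1 higher (9 and 1 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 9.49e-10, and 0.0131 with an estimated correlation). ITGA6 stood at 362 ± 49.3 CPM with PRL-295 and 1005 ± 173 CPM with CDDO-Me (adjusted p = 0.000527), and KRT14, a basal keratin, at 3459 ± 93.4 and 6018 ± 621 CPM (adjusted p = 0.00352). KRT15 was the higher gene (1.88, adjusted p = 0.000172). Of 27 wound edge genes, 8 were lower and none higher (15 lower and 3 higher adjusted over the list alone), with a median of -0.51 (camera adjusted p = 3.37e-09, and 0.0131 with an estimated correlation). KRT16 (ENSG00000186832; chromosome 17, 41609778 to 41615899) stood at 64.4 ± 5.52 CPM with PRL-295 and 289 ± 76.6 CPM with CDDO-Me (adjusted p = 0.00743), and MMP1 at 5.38 ± 1.26 and 18.5 ± 5.32 CPM (adjusted p = 0.0112, and 0.058 without PRL-295 3). KRT14 and KRT16 have close paralogs, so reads may be shared between them. KRT1 was lower with PRL-295 (log2 fold change -5.05, adjusted p = 0.0137, with 0.0637 without PRL-295 2 and 0.0718 without PRL-295 3). In its differentiation list 2 genes were lower and 1 higher (6 and 1 adjusted over the list alone; list adjusted p = 0.00718; adjusted p = 0.199 with an estimated correlation). No replication gene passed over all genes and 7 of 18 were higher adjusted over the list alone (list adjusted p = 7.59e-05; adjusted p = 0.13 with an estimated correlation). Of 22 interferon-stimulated genes 1 was higher with PRL-295 (2 adjusted over the list alone), IFIT3 at 0.78 (list adjusted p = 0.00398; adjusted p = 0.418 with an estimated correlation). That list call ended without CDDO-Me 2 (0.0622), and the IFIT3 call without CDDO-Me 3 (0.0606), PRL-295 1 (0.0809) or PRL-295 3 (0.0718). The inflammatory cytokine list had 3 higher genes over all genes and adjusted over the list alone (list adjusted p = 0.0102; adjusted p = 0.347 with an estimated correlation), CCL2 (2.84, adjusted p = 0.000168) and IL1B, interleukin 1 beta (1.88, adjusted p = 0.00261), among them. The median of this list was 0.158, with 0.052 and 0.305 without CDDO-Me 1 and 2 and -0.043 without PRL-295 1. Fry did not call it (adjusted p = 0.0654).

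**Figure D3:**
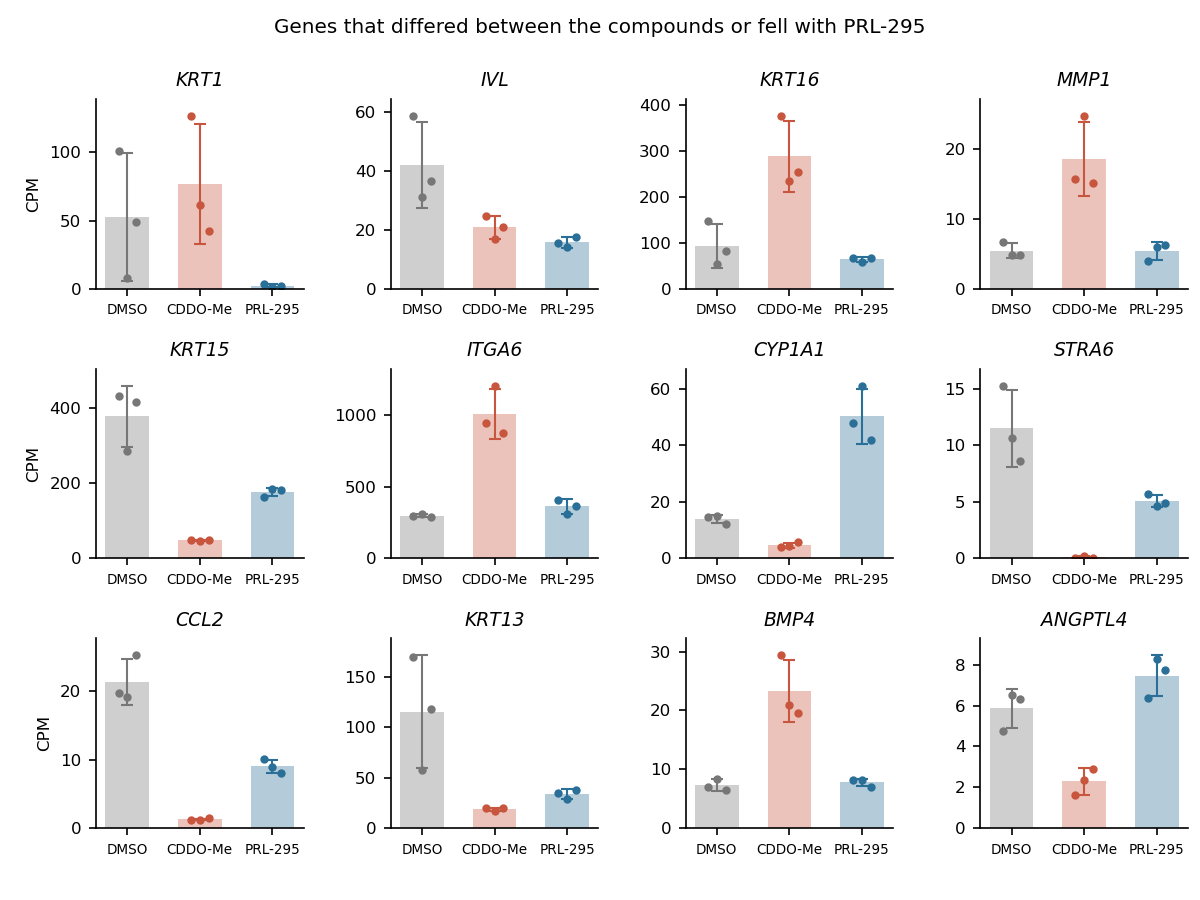
CPM of single genes in each library by group, with the group mean. CYP1A1 stands at 14.0 ± 1.44 CPM with DMSO, 4.66 ± 0.92 CPM with CDDO-Me and 50.2 ± 9.76 CPM with PRL-295.

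The integrated stress response list was higher with PRL-295, with 2 of 20 genes past the threshold (3 adjusted over the list alone), the amino acid transporter subunits SLC7A5 (0.81) and SLC3A2 (0.69) (list adjusted p = 0.00814; adjusted p = 0.308 with an estimated correlation). Its call ended without PRL-295 2 (0.0839) and, narrowly, with a GC and length correction (median 0.118, camera adjusted p = 0.0501). The SLC3A2 call ended without PRL-295 3 (0.0532), and the SLC7A5 call without DMSO 2 (0.0519), CDDO-Me 3 (0.101), PRL-295 1 (0.0532), PRL-295 2 (0.0673) or PRL-295 3 (0.0916). The growth factor list was lower, with 1 gene higher and BMP4 lower (-1.58; 2 higher and 5 lower adjusted over the list alone; list adjusted p = 0.00408; adjusted p = 0.0808 with an estimated correlation), and the BMP4 call ended without PRL-295 3 (0.0532). The p53 target list was lower with no gene past the threshold (5 lower and 1 higher adjusted over the list alone; list adjusted p = 0.00718; adjusted p = 0.0693 with an estimated correlation). The cholesterol list was lower with a median of -0.31 (list adjusted p = 0.0221; adjusted p = 0.0967 with an estimated correlation), although its 1 called gene, the sterol reductase DHCR7, was higher (1 higher and 1 lower adjusted over the list alone). That list call ended without PRL-295 1 (0.0754) or PRL-295 3 (0.0635), and the DHCR7 call without DMSO 2 (0.0532), CDDO-Me 3 (0.0601), PRL-295 1 (0.0532), PRL-295 2 (0.0921) or PRL-295 3 (0.118).

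In the direct comparison edgeR called 258 genes, 147 higher and 111 lower with PRL-295, of which 58 and 52 differed at least 2-fold. The balance turned to 139 higher and 142 lower with library-size scaling and to 299 higher and 332 lower with a GC and length correction. Genes called higher had a median GC content of 55.9% and those called lower 49.6%, and after a GC and length correction 236 of the 258 calls remained among 631. The count was 164 without DMSO 1, 130 without DMSO 2, 167 without DMSO 3, 106 without CDDO-Me 3, and 125, 110 and 60 without PRL-295 1, 2 and 3.

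The calls for the compounds against DMSO overlapped. Of the 96 genes called for both against DMSO, 95 moved in the same direction, 68 higher and 27 lower, and CYP1A1 moved in opposite directions. The shared genes included AKR1C1, TXNRD1, GCLC, OSGIN1 and PGD. Independent calls would share 3.49 higher and 1.64 lower genes, and simulated unchanged groups compared with the same control libraries shared 0.02 genes on average, at most 1 in 50 simulations. Those groups gave only 0.18 and 0.1 calls on average, at most 2 for each, so they say nothing of the overlap expected at 1497 and 111 calls. Part of the excess can come from the shared controls. The fold changes correlated across genes with r = 0.592 (simulated mean 0.498, range 0.473 to 0.524), with a covariance of 0.333 against 0.238 simulated. Genes are not independent replicates. The simulation drew genes independently and without the GC trend that set the DMSO libraries apart, so the excess is no evidence of a shared response. With the GC and length correction r was 0.541, and without CDDO-Me 2 it was 0.445. Among 1512 genes called for either compound, 217 passed the direct test, 210 of them moved further from DMSO by CDDO-Me, such as HMOX1, STRA6 and ITGA6, and 7 by PRL-295. Of the 1512, 1497 were called for CDDO-Me, and the direct test uses the same CDDO-Me libraries, so the selection itself favours that split. A further 41 genes passed the direct test and were called for neither compound. Of the genes called for CDDO-Me alone, 687 higher and 714 lower, 202 passed the direct test, as did 5 of the 15 called for PRL-295 alone. The F test called 922 genes as differing among the 3 groups.

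The shared count was 34, 35 and 43 without DMSO 1, 2 and 3, 450 and 57 without CDDO-Me 1 and 3, and 39, 56 and 30 without PRL-295 1, 2 and 3. The count past the direct test was 127, 99 and 124 without DMSO 1, 2 and 3, 93 without CDDO-Me 3, and 112, 105 and 54 without PRL-295 1, 2 and 3, and the F test count was 313, 287, 404, 1919, 595, 408 and 372 without DMSO 1, 2 and 3, CDDO-Me 1, 2 and 3, and PRL-295 3.

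**Figure D4:**
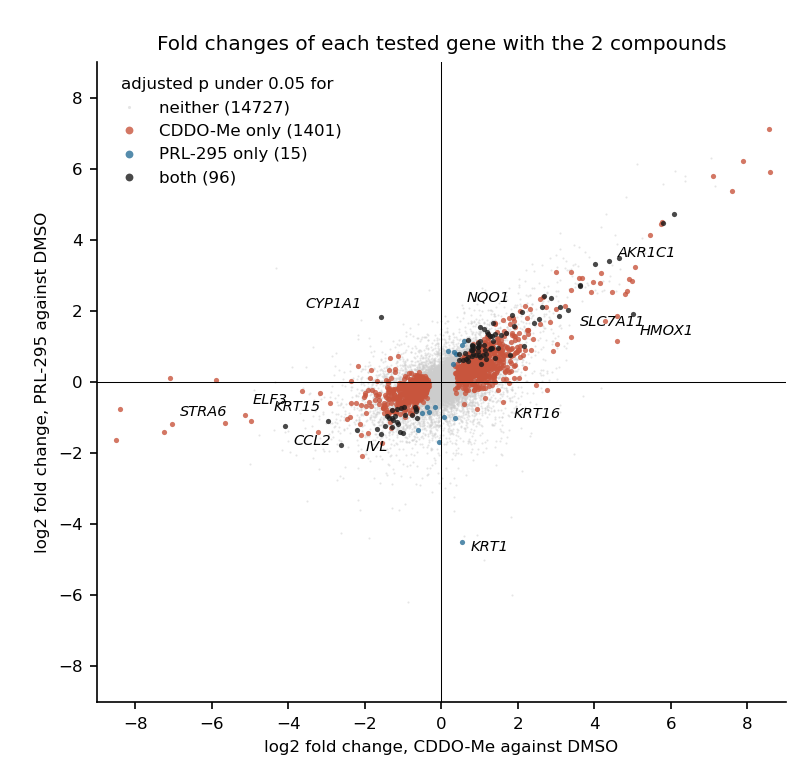
Log2 fold change of each of the 16239 tested genes against DMSO, with CDDO-Me on the horizontal axis and PRL-295 on the vertical axis, coloured by call. The fold changes correlate across genes with r = 0.592, and CYP1A1 was called in opposite directions.

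Markers of other cell types were low in all groups. The highest mean over all libraries among fibroblast markers was 9.68 CPM for COL1A1, among melanocyte markers 3.55 CPM for MITF, among immune cell markers 2.28 CPM for CD74 and among endothelial markers 0.892 CPM for VWF. Of the lists' genes, 1 of 9, 3 of 7, 2 of 7 and 1 of 5 were tested, none passed the edgeR threshold over all genes in any comparison, and camera called none of the 4 lists. Adjusted over the list alone, 1 immune cell gene, CD14, was lower with CDDO-Me than with DMSO or PRL-295, and COL1A1 was lower with PRL-295 than with CDDO-Me. Fry, which compares no list with other genes, gave the immune cell list an adjusted p of 0.000511 (lower with CDDO-Me than with DMSO) and 0.00102 (higher with PRL-295 than with CDDO-Me). It gave VWF, the endothelial list's tested gene, 0.0451 (lower with CDDO-Me than with DMSO), and COL1A1 0.0451 and 0.0118 (lower with PRL-295 than with DMSO and than with CDDO-Me).

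**Figure D5:**
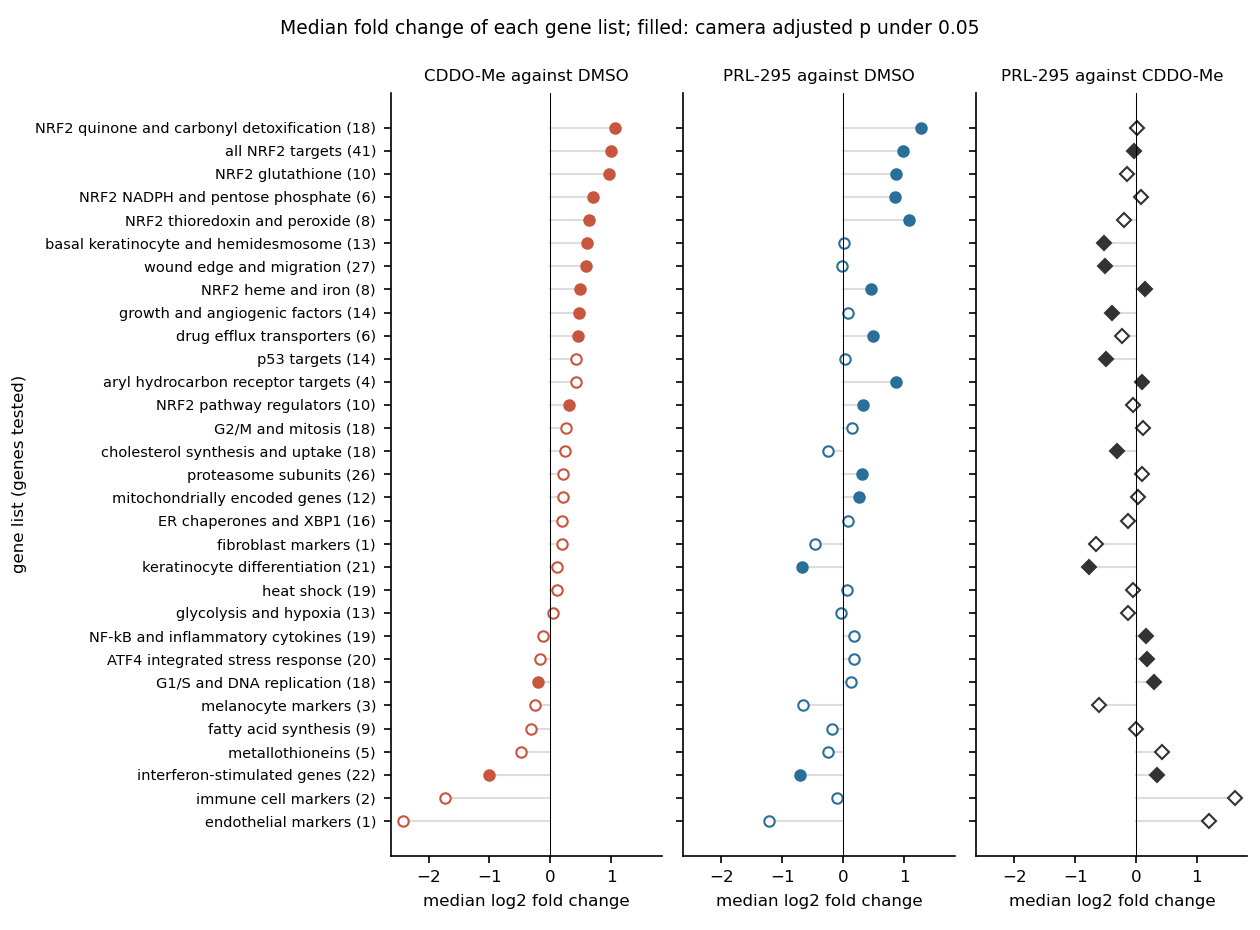
Median log2 fold change of each of the 31 gene lists in the 3 comparisons; filled points have a camera adjusted p under 0.05 at the preset correlation. The NRF2 targets have medians of 0.995 with CDDO-Me and 0.98 with PRL-295 against DMSO, and -0.03 in the direct comparison.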

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

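The GC and length correction, its combination with the block and the fits without CDDO-Me 1 and PRL-295 2 were chosen after the data were seen. The counts for CDDO-Me against DMSO, PRL-295 against DMSO and PRL-295 against CDDO-Me, and those from the F test, shared by both compounds and past the direct test, were 1497, 111, 258, 922, 95 and 217 as reported. They stayed within 1.5 times with RLE (1481, 111 and 247 for the comparisons), library-size scaling (1496, 114 and 281), a minimum of 1 CPM (1654, 121 and 278) and limma on FPKM with a pseudocount of 1 (1451, 75 and 268) or 0.1 (1383, 75 and 234). The CDDO-Me split of 755 higher and 742 lower moved both ways. It was 560 and 891 on FPKM (pseudocount 1; 536 and 847 with 0.1), but 1676 and 833 without a filter, 1389 and 1129 with DESeq2, 352 and 166 with a fold threshold of 2, and 760 and 632 with the GC and length correction. In the same order they were 2509, 825, 1250, 2841, 549 and 899 without a filter, and 2518, 539, 897, 2387, 356 and 664 with DESeq2. A fold threshold of 2, which by construction only removes genes, gave 518, 62, 110, 387, 46 and 82, and no value for the correlation, which it does not enter. With the GC and length correction the counts for PRL-295 against DMSO and the direct comparison were 266 and 631, with 217 shared and 497 past the direct test; the corresponding comparison counts with a block as well were 234 and 539. Without CDDO-Me 1 and PRL-295 2 together they were 4219, 978, 3381 (F test) and 864 (shared), and the direct count was 253. Fits of only the 6 libraries compared gave 650 for PRL-295 against DMSO and 45 for the direct comparison. The cause of these shifts was not tested.

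The replicate numbers showed no clear pairing of the samples: 3 of 9 same-number correlations exceeded 0.1 (-0.379 to 0.297), and 3 of 9 samples correlated best with their own number. These correlations also carry the GC trend of each library, so they cannot exclude a pairing. A replicate block gave 864, 60, 156, 459, 51 and 129.

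Leaving out each library gave 400 to 2803, 33 to 589, 60 to 285, 287 to 1919, 30 to 450 and 54 to 269, with a correlation of 0.445 to 0.767. The number of libraries per group falls to 2 there, and the fit assumes a common spread. In all of those fits, 54 of 99 called named genes kept their call for CDDO-Me, 21 of 49 for PRL-295 and 15 of 41 in the direct comparison, as did 12 of 13, 12 of 13 and 8 of 13 lists. In the same order of comparisons, the replicate block ended 27, 16 and 10 of these named-gene calls, limma on FPKM 16, 10 and 5 (pseudocount 1) and the GC and length correction 17, 0 and 1. The block ended those of the proteasome genes PSMA4, PSMC6 and PSMD12 and the p53 targets CDKN1A and RRM2B for CDDO-Me against DMSO, and of ABCC3 (adjusted p = 0.0654) and MAFG (0.0549) for PRL-295 against DMSO and IFIT3 (0.0641) in the direct comparison. With an estimated correlation 3 of 13 direct list calls remained, and the NRF2 target list (median -0.03) lost its direct call (adjusted p = 0.418), as it did with fry (0.135). Leaving out each library put its median at -0.036 to 0.089, whereas it was -0.13 (adjusted p = 1.49e-06) with the GC and length correction and -0.139 (5.1e-06) without CDDO-Me 1 and PRL-295 2. With the GC and length correction the mitochondrially encoded list (PRL-295 against DMSO) turned from 0.254 to -0.151 (adjusted p = 0.251), and FASN in the direct comparison from -0.06 to 0.25 (adjusted p = 0.0424); the cause was not tested. Over all named genes and alternatives, 4486 values kept direction and side of the threshold, 614 fell short of it, 39 passed it newly, 52 moved and 1 reversed. For lists these were 1548, 37, 52, 33 and 1. At this depth, genes changed 1.5-fold were mostly missed in simulated data (4% and 10% recovered).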

Other observations

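The tests of the number of genes called (GC trend and spread) were chosen after that result was seen, as were the genes of retinoid metabolism named here individually. Retinoid genes fell with CDDO-Me beyond STRA6, DHRS3 and ELF3. A list of 23 other genes of retinoid response and metabolism, 15 of them tested, was written after those 3 had been seen and before its own values were. Of the 15, 6 fell and none rose with CDDO-Me against DMSO, with a median of -0.55 on the log2 scale, and 11 lay below 0. They were ALDH1A3, which makes retinoic acid (log2 fold change -1.32, adjusted p = 4.62e-05), the keratins KRT19 (-1.62) and KRT4 (-2.09), the retinoic acid receptor gene RARG (-0.87), and CYP26B1 (-0.72) and CYP26A1, which degrade retinoic acid. CYP26A1 had 127 counts over the DMSO libraries and 0 over the CDDO-Me libraries, so it was at least 40.2-fold lower (floor of 3 counts over the group); the median is the same with that bound. The list was not tested for PRL-295 against DMSO, so whether it also fell there stays open. In the direct comparison 4 of the 15 were higher with PRL-295, ALDH1A3 (1.44) and KRT19 (1.01) among them, and none lower. KRT4 (0.015, edgeR adjusted p = 0.995) and RARG (0.458, 0.0855) did not pass in it, so their fall is not shown to be particular to CDDO-Me. The differences of KRT4, RARG, KRT19 and CYP26A1 in it were smaller than their falls with CDDO-Me. By these estimates those genes also lay below DMSO with PRL-295, whereas ALDH1A3 and CYP26B1 did not. The median there was 0.205 (0.113 with a GC and length correction), and 4 of the 15 lay below 0. It was 0.326 without DMSO 1, 0.395, 0.408 and 0.488 without CDDO-Me 1, 2 and 3, and 0.311 without PRL-295 2, but 0.014 without PRL-295 1.

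A candidate explanation is lower retinoic acid signalling with CDDO-Me. The list was lower than other genes by camera (adjusted p = 6.35e-06 over the 2 comparisons tested; 0.00502 with an estimated correlation), and higher with PRL-295 than with CDDO-Me (7.32e-05; 0.00547 with an estimated correlation), but both comparisons use the same 3 CDDO-Me libraries, so the direct one is not independent support. Without CYP26A1, left out after its counts were seen, the adjusted p was 5.22e-05 and 0.000704 (0.00846 and 0.0113 with an estimated correlation) and the median -0.383 and 0.152. The highest adjusted p on leaving out a library was 0.000151 (without CDDO-Me 3) and 0.00209 (without CDDO-Me 2), and with a GC and length correction 1.28e-05 and 0.000103. RARA (-0.02), TGM2 (0.13), RDH10 (0.46) and LRAT (0.11) did not pass, retinoic acid itself was not measured, and a direct effect on these genes stays open.

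More genes were called for CDDO-Me (1497) than for PRL-295 (111). With the GC and length correction the counts were 1392 and 266, so the gap was smaller with it. After the GC and length correction the ratio of the counts was 5.23 (3.28 without CDDO-Me 1 to 10.5 without PRL-295 2), above the bound of 1.5, which argues against the GC trend as its whole cause. The median spread of log2 CPM among PRL-295 libraries was 0.598 times that among CDDO-Me libraries, so it was not larger with PRL-295. Both counts come from a single fit in which all 9 libraries share an estimate of each gene's spread. A group's own spread cannot set its own count there, so this test does not decide whether spread contributes to the gap. Fits of only the 6 libraries compared share no estimate with the third group. They gave 1231 and 650, against 1497 and 111 in the single fit. Much of the gap thus depended on fitting all 9 libraries together. The CDDO-Me libraries, which enter the shared estimate, had the largest median SD of log2 CPM (0.244, against 0.146 in each other group). Calls for PRL-295 against DMSO thus also depended on libraries outside that comparison, with 589, 272 and 62 without CDDO-Me 1, 2 and 3. The fits of 6 libraries also filter and scale anew, so the exact part of the shared estimate in the gap was not separated. The unequal doses, and DMSO that the labels list for the control only, stay open as untested.

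Interferon-stimulated genes were lower with both compounds than with DMSO. Of 10000 random lists matched on GC content, length and expression, 0% had a median as low in either comparison, which argues against the GC trend. The highest median without 1 DMSO library was -0.678 (PRL-295, without DMSO 3), against 1 DMSO library as the source. Both comparisons use the same 3 DMSO libraries, so something common to the control cultures, such as a different DMSO content or an interferon response in them, stays open beside an effect of the compounds.

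Basal and wound edge genes were lower with PRL-295 than with CDDO-Me. Of 10000 matched lists 0% had a median as low for either list, against medians of -0.528 and -0.514, which argues against the GC trend. The highest median without 1 library was -0.444 (basal list, without PRL-295 2), which argues against 1 library as the source. The doses differ, so a difference between compounds and one between doses stay open.

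Other splits of the libraries were tested for each count. With 10 splits of 6 libraries the share can never fall under 0.05. The real values and the highest of the other splits were 1497 and 0 genes for CDDO-Me against DMSO, 111 and 0 for PRL-295 against DMSO, and 258 and 0 for the direct comparison; for lists they were 13 and 7, 13 and 11, and 13 and 6, and in each case 1 split, the real one, gave a result as large. For 100 of the splits of the 9 libraries into 3 groups, 1 split, the real one, gave as many genes in the F test (922, highest other 136). This argues against chance as the source of all differences among the groups. For the genes past the direct test it was also 1 split (217, highest other 88). Those splits mix all 3 groups, so a difference of CDDO-Me from DMSO alone could make the real split stand out. They therefore cannot exclude chance for the direct comparison. For the calls shared by both compounds 2 splits, the real one included, gave a result as large, and the other gave more (104) than the real 95.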
